A study of Mus musculus with 7 samples.

How the data were processed

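RNA was measured in 7 libraries of cells sorted from B16 tumours (a mouse melanoma line) 5 days after treatment. Per the labels' protocols, live cells lacking CD45 (the common leukocyte surface marker) and CD31 (an endothelial marker) were sorted, and poly(A) RNA was sequenced with a kit that keeps strand. Of these libraries, 3 came from mice given radiotherapy at 8 Gy with the vector AAV-iIL12 and 4 from mice given the same radiotherapy with the control vector AAV-iLuc. AAV is adeno-associated virus, a vector for gene delivery. The series' design text counts the libraries of each group as mice, so the spread between them was taken as the spread between animals.

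The deposited values were raw fragment counts per gene. Per the file headers, the authors made these counts with featureCounts 1.6.0 over exons summed by gene, with the reverse-stranded and paired-end settings and the GENCODE vM32 annotation. No option for reads that map to several places was set in those headers, so genes with near-identical copies, such as guanylate-binding proteins, Tgtp1 and Tgtp2 or class I MHC genes, may be undercounted or uneven. Per the submitters' processing notes, FastQC 0.11.8, STAR 2.7.9a, the genome build GRCm39, edgeR and limma were also used. Each file held 56953 genes, and every row named a gene. Symbols and gene types came from the GENCODE vM21 annotation by gene identifier, which matched 52029 identifiers holding 99.4% of counts. Coordinates are those of the files, on GRCm39. Total counts ranged from 16356653 to 19080587 per library.

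The groups were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test on the deposited counts, with TMM normalization, the filterByExpr filter, and Benjamini-Hochberg adjustment at 0.05. The filter left 13990 genes. Expression is given as CPM from the cpm function of edgeR, scaled by TMM. Values are given as mean ± SD CPM with n = 3 for AAV-iIL12 and n = 4 for AAV-iLuc, and log2 fold changes as AAV-iIL12 over AAV-iLuc with a standard error derived from the F statistic. The 22 gene lists and 13 cell type lists were fixed before the data were examined. The 28 lists with at least 3 tested members were tested as sets with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over those lists, and again with an estimated correlation and with fry. Shares of counts, totals and summed CPM of the cell type lists made 20 composition measures. These were compared by a two-sided exact permutation test over all 35 splits of the 7 libraries into 3 and 4, where the smallest p is 0.0286. Principal components and Spearman correlations used log2 CPM with a prior count of 2.

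Genes were named by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between groups, leaving out predicted genes without a standard symbol. From each list past the camera threshold it took the 4 members with the smallest p and the member with the highest mean CPM, and from any other list the 3 most abundant members. Il12a, Il12b and Ifng were always included. Where other members are named, they were chosen after their values were seen. A gene at 0 in every library of a group is bounded with a floor of 3 counts over the group. Genes with 1 to 3 counts are given as a ratio with an exact 95% binomial interval, which covers counting error only.

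On counts simulated for 13990 genes at the real library sizes, the gene test recovered 86% of genes raised 2-fold, 94% of those raised 4-fold, 74% of those lowered to 0.5 and 88% of those lowered to 0.25, and 4.59% of its calls were genes simulated as unchanged. Only 200 genes were changed by these folds, as many up as down, and 25 by 1.5-fold, with no library set apart. In the data 47.2% of tested genes were called, so these rates need not hold there. Alternatives were median-of-ratios size factors, library size only, upper quartile, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, a threshold of 0.01, a minimum absolute log2 fold change of 1, the replicate number as a block, a covariate from leukocyte genes, and each library left out. Counts of each pair of libraries in a group differed by more than sampling noise, so no library was treated as a duplicate. The labels give no sequencing batch. The deposited files hold gene counts, so vector sequence was not analysed here.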

Results

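Gene expression was measured in CD45-negative CD31-negative cells from irradiated B16 tumours, to compare mice given AAV-iIL12 with mice given the control AAV-iLuc 5 days after treatment. The vector AAV-iIL12 is named for interleukin 12, a cytokine that drives interferon gamma production by T and NK cells. All 7 mice had received 8 Gy. The 3 AAV-iIL12 libraries held 17057054, 19080587 and 18903109 counts. The 4 AAV-iLuc libraries held 18705849, 18009824, 16356653 and 18694560 counts.

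Melanocyte genes were the most abundant genes of the fixed lists in both groups, with Dct at 8132 ± 161 CPM in AAV-iIL12 and 7880 ± 326 CPM in AAV-iLuc. Interferon, antigen presentation and complement genes were higher in AAV-iIL12 tumours, and genes of DNA replication and mitosis were lower. Of 13990 genes tested, 3292 rose and 3316 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The rises were larger than the falls: 333 genes rose and 93 fell at least 4-fold, and 121 rose and 3 fell at least 16-fold. The groups did not overlap for 7351 genes, 52.5% of those tested, where chance gives 5.71% per gene. Genes measured in the same libraries are not independent, so that rate is no yardstick for their number. Between libraries of 1 group the Spearman correlation lay between 0.991 and 0.997, and between groups it lay between 0.935 and 0.971. With library size as the only scaling, 2506 genes rose and 4460 fell, so that 36.0% of calls were higher against 49.8%, and with upper quartile scaling 38.5% were higher.

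**Figure D1:**
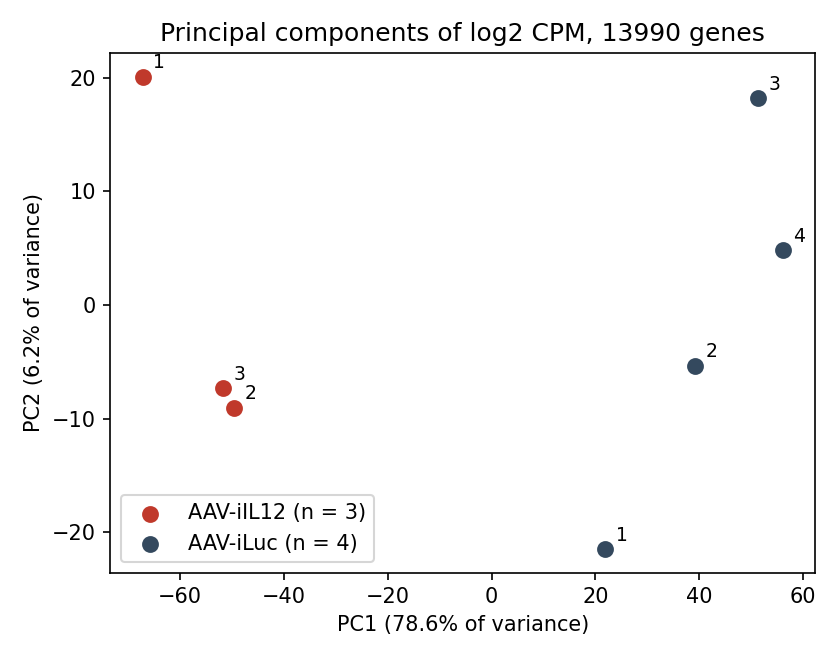
Principal components of log2 CPM over the genes tested, with 1 point per library labelled by replicate number and the share of variance on each axis. The first component (78.6% of variance) separates the 3 AAV-iIL12 libraries, at -67.2 to -49.6, from the 4 AAV-iLuc libraries, at 21.9 to 56.1, and AAV-iLuc replicate 1 lies nearest to the AAV-iIL12 libraries.

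Both subunit genes of interleukin 12 were detected in every AAV-iIL12 library and were near absent from the AAV-iLuc libraries. Il12a (ENSMUSG00000027776, chromosome 3, 68597977 to 68605880, GRCm39) reached 14.9 ± 0.82 CPM in AAV-iIL12. It had 791 counts there and 0 counts in the 4 AAV-iLuc libraries, so it was at least 366-fold higher, with a floor of 3 counts over the group. Il12b (ENSMUSG00000004296, chromosome 11, 44290890 to 44304860) reached 22.1 ± 2.65 CPM, with 1168 counts against 2, a ratio of 811 with a 95% interval of 224 to 6706. Both genes passed the edgeR test (adjusted p = 1.49e-06 for Il12a and 3.80e-07 for Il12b). Both Il12b counts outside the AAV-iIL12 group were in AAV-iLuc replicate 1. Ifng, the gene of interferon gamma, had 32 counts against 1, too few to pass the filter, with a ratio of 44.5 and a 95% interval of 7.43 to 1810. Gene-level counts do not tell a vector transcript from the endogenous one.

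Guanylate-binding proteins and class II MHC genes made up most of the 12 largest rises. Gbp8 (ENSMUSG00000034438, chromosome 5, 105162016 to 105287406), a guanylate-binding protein, rose from 1.26 ± 2.42 to 150 ± 30.6 CPM, a log2 fold change of 6.83 ± 0.61 (SE, adjusted p = 1.69e-05). Gbp10, Gbp5, Gbp4, Gbp2 and Gbp9 rose by 6.30, 6.10, 5.86, 5.73 and 5.66 on the log2 scale, and Apol6, of the apolipoprotein L family, by 6.41. H2-Aa rose from 10.1 ± 17.8 to 776 ± 251 CPM and Cd74, the invariant chain of class II MHC, from 25.6 ± 43.2 to 1787 ± 538 CPM. H2-Ab1, H2-Eb1 and Ciita, the transactivator of class II genes, rose by 6.14, 5.88 and 6.09. The SDs in AAV-iLuc came mostly from replicate 1, where H2-Aa stood at 36.7 CPM against at most 2.58 CPM in the other libraries of its group. Without that library the log2 fold changes of 11 of these genes rose to between 7.30 (Gbp2) and 9.34 (H2-Aa), and Gbp8 was left with 3 counts in the control group.

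All 39 tested members of the interferon gamma response list rose, also when adjusted over the list alone. Their median log2 fold change was 4.68, and it was 6.01 without AAV-iLuc replicate 1. The call of Gch1 ended without AAV-iIL12 replicate 1 or 3 or AAV-iLuc replicate 3 (edgeR adjusted p = 0.0728, 0.0898 and 0.0515), and that of Nos2 without AAV-iIL12 replicate 1 (0.0520). Igtp, an interferon-inducible GTPase and the most abundant member, rose from 53.9 ± 82.2 to 2217 ± 201 CPM (log2 fold change 5.36, and 7.41 without AAV-iLuc replicate 1). Wars, a tryptophanyl-tRNA synthetase, rose from 143 ± 5.75 to 439 ± 32.2 CPM. Socs1, which restrains cytokine signalling, rose from 1.61 ± 0.77 to 26.3 ± 3.84 CPM, and Cxcl10 from 24.6 ± 8.81 to 400 ± 137 CPM. The camera adjusted p of the list was 2.81e-18, with adjusted p = 0.242 with an estimated correlation.

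The type I interferon list behaved likewise, with 28 of 28 members higher, also adjusted over the list alone, and a median of 3.25. The call of Ifi27l2a ended without AAV-iIL12 replicate 1 and with the leukocyte covariate (edgeR adjusted p = 0.0735 and 0.122). Ifit2 rose from 41.2 ± 5.92 to 381 ± 74.3 CPM, Oas3, which senses double-stranded RNA, from 1.34 ± 0.67 to 58.4 ± 17.7 CPM, and Mx1 from 2.19 ± 0.88 to 60.3 ± 19.6 CPM. Isg15 and Rsad2 rose by 3.40 and 3.34 on the log2 scale. Camera gave an adjusted p of 1.71e-31 (adjusted p = 0.189 with an estimated correlation). Genes of both interferon lists overlap in function, and the counts do not separate the types of interferon.

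Antigen presentation genes rose on both MHC arms. In the class I list 19 of 22 tested members rose, 1 fell and 2 did not pass (19 and 2 adjusted over the list alone), with a median of 3.42 and an adjusted p of 1.32e-19 (adjusted p = 0.189 with an estimated correlation). H2-K1 rose from 277 ± 84.9 to 2554 ± 436 CPM and B2m, the light chain of class I molecules, from 496 ± 188 to 3654 ± 613 CPM. H2-M3 and the proteasome activator genes Psme1 and Psme2 rose by 3.63, 2.60 and 2.56. The member that fell was Canx, a chaperone of the endoplasmic reticulum, by 0.32, and the members that fell were 2 without AAV-iLuc replicate 4 or with upper quartile scaling and 3 with library size only. All 10 tested class II members rose, also adjusted over the list alone, with a median of 5.98, an adjusted p of 2.58e-05 and adjusted p = 0.321 with an estimated correlation. Without AAV-iLuc replicate 1 the median was 8.41. H2-DMa rose from 4.16 ± 5.73 to 201 ± 45.6 CPM, H2-DMb1 from 5.44 ± 3.90 to 126 ± 24.5 CPM and H2-DMb2 from 0.145 ± 0.217 to 12.1 ± 6.25 CPM. Without AAV-iLuc replicate 1 the log2 fold changes of H2-DMa and H2-DMb1 were 7.29 and 5.12 instead of 5.57 and 4.52, and H2-DMb2 was left with 2 counts in the control group. In the AAV-iIL12 libraries and AAV-iLuc replicate 1, leukocyte genes stood at a far lower level than class II genes. The all-leukocytes list, of which 0 of 8 tested members passed in edgeR, summed to 10.2 ± 3.65 CPM in AAV-iIL12. It summed to 13.4 CPM in AAV-iLuc replicate 1 and to at most 3.97 CPM in the other AAV-iLuc libraries. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 together reached at least 2791 CPM in AAV-iIL12 and 173 CPM in AAV-iLuc replicate 1. In AAV-iLuc replicates 2, 3 and 4 they summed to 14.6, 4.17 and 2.83 CPM, so in replicates 3 and 4 leukocyte genes were not far lower.

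**Figure D2:**
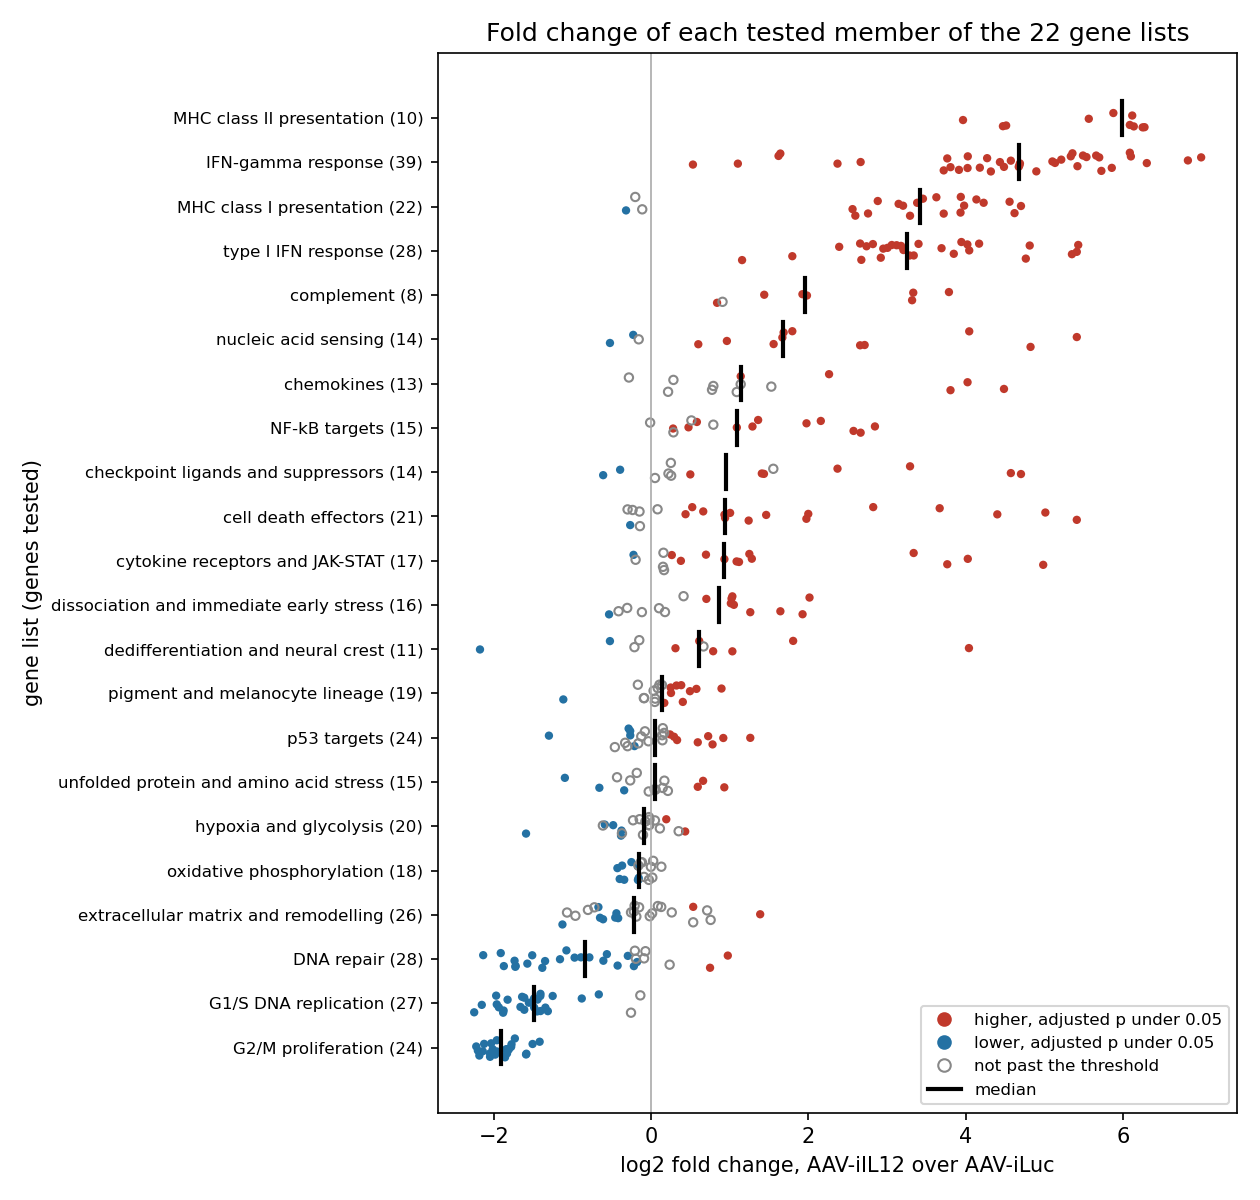
Log2 fold change (AAV-iIL12 over AAV-iLuc) of each tested member of the 22 fixed gene lists, with 1 point per gene and a black bar at the median of each list. Filled points passed the adjusted p threshold of 0.05. Medians run from 5.98 for class II presentation to -1.91 for G2/M proliferation.

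Chemokine genes that attract T cells were among those that rose: Cxcl10 by 4.02, Cxcl11 by 3.81, Cxcl9 by 4.49 (6.28 without AAV-iLuc replicate 1) and Ccl5 by 2.26. Of 13 tested chemokines 5 rose and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00459, adjusted p = 0.321 with an estimated correlation). Among checkpoint ligands and suppressors, Cd274, which encodes PD-L1, rose from 32.4 ± 19.8 to 774 ± 87.2 CPM (log2 fold change 4.58, adjusted p = 1.39e-05). Cd47, which signals against phagocytosis, rose from 59.2 ± 4.13 to 160 ± 3.59 CPM, Lgals9 from 69.0 ± 9.77 to 183 ± 19.2 CPM, H2-T23 from 27.4 ± 15.9 to 716 ± 141 CPM and Tnfrsf14 by 3.29 on the log2 scale. Of its 14 tested members 7 rose, 2 fell and 5 did not pass (9 rose and 2 fell adjusted over the list alone; camera adjusted p = 9.65e-06, adjusted p = 0.231 with an estimated correlation). Lgals3 fell by 0.40 and Tgfb2 by 0.61. The Lgals3 call ended without any library but AAV-iLuc replicate 4 (edgeR adjusted p = 0.0570 to 0.122), and the Tgfb2 call without AAV-iIL12 replicate 2 or 3 or AAV-iLuc replicate 3 or 4 (0.0529 to 0.0899). Tgfb2 also lost its call with the replicate block (edgeR adjusted p = 0.0910). Lgals3 did so with median-of-ratios size factors (0.0533) and in limma-voom (0.0549). With the leukocyte covariate both calls ended (edgeR adjusted p = 0.250 for Lgals3 and 0.128 for Tgfb2) and 0 members of the list fell.

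Il12rb1, a subunit of the interleukin 12 receptor, rose from 4.29 ± 3.30 to 137 ± 5.70 CPM (log2 fold change 4.99, and 5.66 without AAV-iLuc replicate 1). Jak2 rose from 49.2 ± 3.92 to 120 ± 5.68 CPM and Stat3 from 559 ± 36.0 to 1066 ± 8.91 CPM. In this list of cytokine receptors and JAK-STAT genes, 12 of 17 tested members rose, 1 fell and 4 did not pass (13 rose and 2 fell adjusted over the list alone; camera adjusted p = 7.50e-08, adjusted p = 0.189 with an estimated correlation). The member that fell was Ifngr2, a subunit of the interferon gamma receptor, by 0.23, and the members that fell were 2 without AAV-iLuc replicate 2, with library size only or with upper quartile scaling.

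NF-kB targets rose in 11 of 15 cases and none fell, also adjusted over the list alone (camera adjusted p = 4.91e-06, adjusted p = 0.242 with an estimated correlation). Nfkbia, an inhibitor of NF-kB, rose from 12.5 ± 1.38 to 90.1 ± 21.3 CPM, and Nfkbie, Icam1, Tnfaip3 and Tnip1 by 1.98, 2.66, 1.29 and 0.28. The call of Il6 ended in edgeR without AAV-iIL12 replicate 1 and with the replicate block (adjusted p = 0.0586). Complement genes rose in 7 of 8 cases, also adjusted over the list alone (camera adjusted p = 1.10e-09, adjusted p = 0.189 with an estimated correlation). C4b rose from 250 ± 74.0 to 2521 ± 441 CPM, C2 from 82.1 ± 11.5 to 324 ± 42.3 CPM, C1ra from 17.2 ± 4.54 to 172 ± 27.4 CPM and Serping1, a complement inhibitor, by 3.79 on the log2 scale.

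Sensors of nucleic acids and effectors of cell death also rose. In the sensing list 11 of 14 tested members rose, 2 fell and 1 did not pass, also adjusted over the list alone (camera adjusted p = 1.70e-10, adjusted p = 0.189 with an estimated correlation). Zbp1, a sensor of Z-form nucleic acids that is also in the cell death list, rose to 406 ± 48.7 CPM (log2 fold change 5.41, and 7.38 without AAV-iLuc replicate 1). Samhd1, Eif2ak2, Adar and Dhx58 rose by 2.72, 1.56, 1.67 and 4.05, while Cgas fell by 0.53 and Mavs by 0.23. The Cgas call ended without AAV-iIL12 replicate 1 or AAV-iLuc replicate 1 or 3 (edgeR adjusted p = 0.0681, 0.0514 and 0.0585). The Mavs call ended without AAV-iIL12 replicate 1 or 2 (0.0534 and 0.0731) and with the replicate block (0.0800). In the cell death list 15 of 21 tested members rose, 1 fell and 5 did not pass (15 and 2 adjusted over the list alone; camera adjusted p = 1.70e-10, adjusted p = 0.189 with an estimated correlation). Gsdmd, a pore-forming effector of pyroptosis, rose from 3.68 ± 1.96 to 78.6 ± 15.3 CPM, Mlkl, an effector of necroptosis, from 48.2 ± 9.14 to 193 ± 12.9 CPM, and Tnfsf10, the death ligand TRAIL, from 0.451 ± 0.464 to 15.1 ± 2.19 CPM (log2 fold change 5.01, and 6.06 without AAV-iLuc replicate 1). Pycard rose by 1.24. The member that fell was Bax, by 0.27. In this list 2 fell without AAV-iLuc replicate 4 and 3 with library size only or upper quartile scaling, while 3 of the sensing list fell with these scalings. With the leukocyte covariate 0 members of either list fell. The calls of Bax, Cgas and Mavs ended there (edgeR adjusted p = 0.0526, 0.0686 and 0.137).

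Cell cycle genes were lower in AAV-iIL12 tumours. All 24 members of the G2/M list fell, also adjusted over the list alone, with a median log2 fold change of -1.91 (camera adjusted p = 6.65e-22, adjusted p = 0.231 with an estimated correlation). Top2a, a DNA topoisomerase, fell from 417 ± 64.7 to 156 ± 41.7 CPM, Tpx2 from 113 ± 17.5 to 33.9 ± 6.26 CPM and Cdc20 from 48.5 ± 8.67 to 10.5 ± 2.66 CPM. Ccnb2 and Bub1b each fell by 1.59. In the G1/S list 25 of 27 members fell and 2 did not pass, also adjusted over the list alone, with a median of -1.49 (camera adjusted p = 6.82e-23, adjusted p = 0.223 with an estimated correlation). Mcm2, a subunit of the replicative helicase, fell from 365 ± 41.3 to 115 ± 27.6 CPM, and Mcm4, Mcm5, Cdt1 and Ccne1 fell by 1.64, 1.88, 1.62 and 1.41.

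DNA repair genes mostly fell: 21 of 28 fell, 2 rose and 5 did not pass (21 fell and 3 rose adjusted over the list alone), with a median of -0.84 (camera adjusted p = 7.83e-10, adjusted p = 0.242 with an estimated correlation). Chek1, a checkpoint kinase of DNA replication, fell from 24.3 ± 3.33 to 7.34 ± 0.55 CPM, Fanca by 1.73 and Lig1 by 1.39. The members that rose were Atm, the kinase that responds to double-strand breaks, from 102 ± 7.50 to 199 ± 18.7 CPM, and Brca1, from 239 ± 25.7 to 401 ± 48.4 CPM. The most abundant member of the list was Brca1. The call of Xrcc5 ended without AAV-iIL12 replicate 1 or 2 or AAV-iLuc replicate 3, and that of Rad50 without any library but AAV-iIL12 replicate 2 or AAV-iLuc replicate 3 (edgeR adjusted p up to 0.0960 and 0.104).

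The 12 largest falls were led by Mmp15 (ENSMUSG00000031790, chromosome 8, 96078896 to 96101708), a membrane-type matrix metalloproteinase, from 11.2 ± 1.16 to 1.01 ± 0.24 CPM, a log2 fold change of -3.45 ± 0.18 (SE, adjusted p = 1.19e-06). Itga4 (ENSMUSG00000027009, chromosome 2, 79085770 to 79163467), the integrin alpha 4 subunit, fell from 164 ± 23.2 to 23.2 ± 4.62 CPM (-2.82 ± 0.15, adjusted p = 1.19e-06). Zfp469, Prokr1, the collagen gene Col2a1 and Xylt1, a xylosyltransferase of proteoglycan synthesis, fell by 2.76, 2.59, 2.55 and 2.31. Pbk, Depdc1b, Pimreg, Sapcd2, Pif1 and Phf19 fell by between 2.27 and 2.40.

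**Figure D3:**
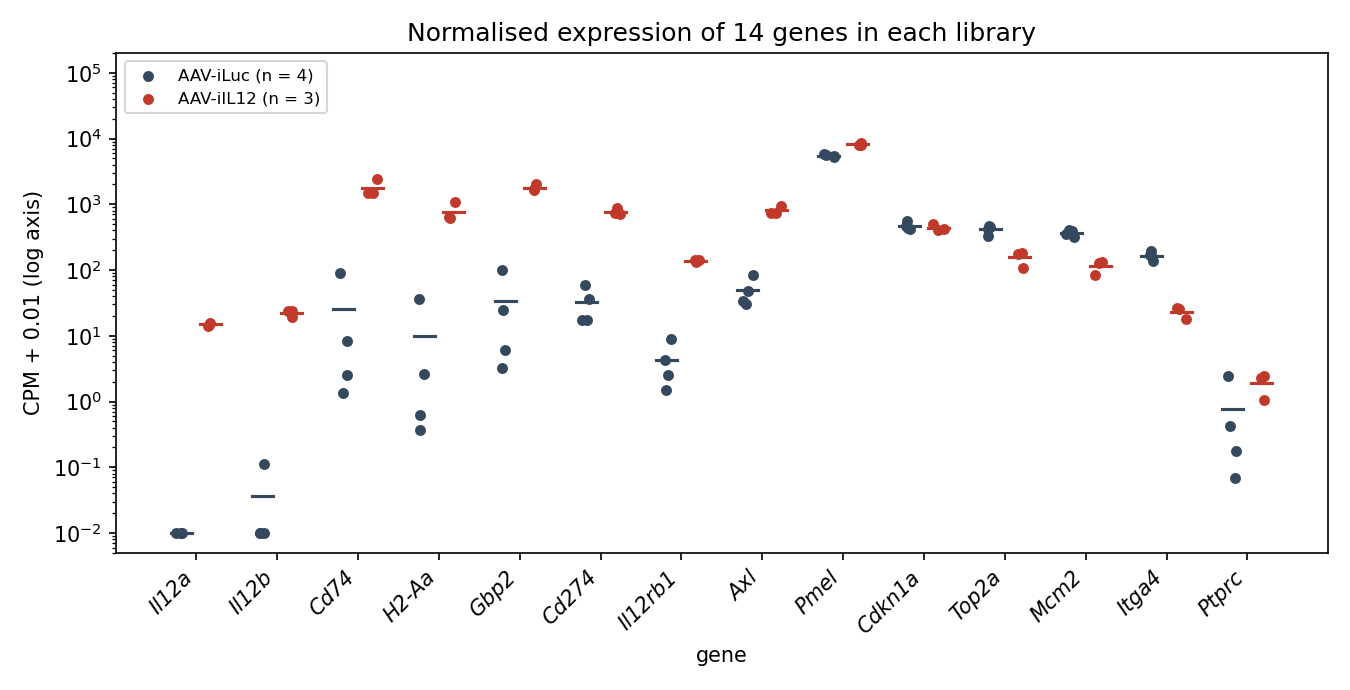
Normalised expression (CPM plus 0.01, log axis) of 14 genes, with 1 point per library and a bar at the group mean. Il12a and Il12b stand at 14.9 and 22.1 CPM in AAV-iIL12 and at or near 0 in AAV-iLuc, where points at the bottom are libraries with no counts. Cd74, H2-Aa and Gbp2 are spread widely over the 4 AAV-iLuc libraries, with replicate 1 highest.

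Immediate early genes rose in 9 of 16 cases, 1 fell and 6 did not pass (10 and 1 adjusted over the list alone; camera adjusted p = 3.67e-04, adjusted p = 0.251 with an estimated correlation). Zfp36, Atf3, Dusp1 and Jun rose by 2.01, 1.64, 1.05 and 1.03, while the heat shock gene Hspa8 stood at 1354 ± 92.2 against 1263 ± 138 CPM and did not pass. This list was fixed as a measure of stress from tissue dissociation.

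The other gene lists did not pass as sets. In the p53 list 8 of 24 members rose and 5 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.604): Cdkn1a, the cell cycle inhibitor p21, stood at 443 ± 58.0 against 468 ± 57.2 CPM, Zmat3 at 130 ± 6.05 against 145 ± 12.3 CPM, and Ccng1 fell by 0.27, a call that ended without AAV-iIL12 replicate 2 or 3 or AAV-iLuc replicate 2 (adjusted p = 0.0915, 0.0887 and 0.0587). Falls in this list numbered 1 without AAV-iIL12 replicate 2, 3 without AAV-iIL12 replicate 3 or AAV-iLuc replicate 2, and 9, beside 7 rises, with library size only or upper quartile scaling. With the leukocyte covariate 5 members rose and 0 fell. Its median of 0.05 was -0.07, 0.08 and 0.12 without AAV-iIL12 replicate 1, 2 and 3, and -0.04 and -0.02 with library size only and upper quartile scaling. In the pigment list 9 of 19 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.204). Pmel, a melanosome structural protein, rose from 5469 ± 237 to 8147 ± 395 CPM, while Tyrp1 at 8120 ± 207 against 7550 ± 592 CPM and Dct did not pass. The member that fell was Kit, a receptor of melanocyte precursors, by 1.12, and 2 fell without AAV-iLuc replicate 4. In the pigment list 7 rose and 3 fell with library size only, and 7 and 2 with upper quartile scaling. In the dedifferentiation and neural crest list 6 of 11 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.138, and 0.0480 without AAV-iLuc replicate 1). Axl, a receptor tyrosine kinase, rose from 49.4 ± 25.1 to 814 ± 120 CPM, Jun from 300 ± 31.7 to 615 ± 40.2 CPM and Sox4 by 0.31, while the members that fell were Nes, by 2.18, and Cdh2, by 0.53.

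In the oxidative phosphorylation list 9 of 18 fell and none rose (10 adjusted over the list alone), with a median of -0.16 and a camera adjusted p of 0.0834, which was 0.0340 without AAV-iLuc replicate 1. The number that fell was 5 without AAV-iIL12 replicate 1 or 3, and 13 with library size only or upper quartile scaling. Atp5a1 fell by 0.43 and Atp5b by 0.17, and Atp5c1 stood at 292 ± 4.24 against 320 ± 7.49 CPM, and passed as lower with library size only, upper quartile scaling, DESeq2 (adjusted p = 0.0312) and limma-voom without and with quality weights (0.0329 and 0.0206). With library size only and upper quartile scaling Zmat3, Pkm, Hspa5 and Mcam passed as lower, and Zmat3 and Mcam also in limma-voom with quality weights (0.0260 and 0.00184). The Atp5b call ended without AAV-iIL12 replicate 1 or 3 or AAV-iLuc replicate 2 or 3 (adjusted p = 0.0528, 0.0626, 0.0581 and 0.0691). Of 20 hypoxia and glycolysis genes 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.312). Gapdh at 5118 ± 296 against 5222 ± 278 CPM and Pkm at 4864 ± 283 against 5122 ± 203 CPM did not pass, and Aldoa rose by 0.19, which did not pass without AAV-iLuc replicate 1 (adjusted p = 0.0718), with library size only (0.0899) or with upper quartile scaling (0.0666). Rises in this list numbered 1 in these settings, and falls 9 and 8 with library size only and upper quartile scaling. In the unfolded protein list 3 of 15 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.976), with a median of 0.04 and a mean of -0.01. The median was -0.04 without AAV-iIL12 replicate 1, -0.07 without AAV-iLuc replicate 1, and -0.05 and -0.03 with library size only and upper quartile scaling, where 5 fell. Hsp90b1 fell by 0.34, while Hspa5 at 987 ± 73.5 against 1121 ± 145 CPM and Pdia4 at 598 ± 15.9 against 533 ± 49.2 CPM did not pass. Pdia4 passed without AAV-iLuc replicate 3 (adjusted p = 0.0109). Of 26 matrix genes 2 rose and 7 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.228). Rises numbered 4 without AAV-iIL12 replicate 3, and 1 without AAV-iIL12 replicate 1 or AAV-iLuc replicate 2 or 4, and with library size only or upper quartile scaling. The median of -0.22 was -0.44 and 0.02 without AAV-iIL12 replicate 1 and 3, and -0.36 and -0.02 without AAV-iLuc replicate 1 and 3. Sparc fell by 0.42, and Fn1 at 395 ± 46.6 against 372 ± 25.3 CPM and Mmp14 at 261 ± 8.50 against 239 ± 9.90 CPM did not pass.

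In the all-leukocytes list 0 of 8 tested members passed (edgeR, also adjusted over the list alone), with Cd37 at 2.09 ± 0.38 against 1.58 ± 0.18 CPM, Ptprc, the gene of CD45, at 1.91 ± 0.76 against 0.770 ± 1.13 CPM and Laptm5 at 1.64 ± 0.91 against 0.927 ± 1.24 CPM. The camera adjusted p of this list was 0.397. Ptprc passed in limma-voom (adjusted p = 0.0343), and without AAV-iLuc replicate 1 Ptprc and Laptm5 passed in edgeR (adjusted p = 0.00137 and 0.0116). In the macrophage list 1 of 10 rose, C1qb, a complement subunit made by macrophages, and none when adjusted over the list alone (camera adjusted p = 0.294). Without AAV-iLuc replicate 1, 4 of 8 tested members rose, with a median of 1.16 instead of 0.74, and without AAV-iIL12 replicate 2 or 3, 2 of 12 rose. The C1qb call ended without AAV-iIL12 replicate 1 or AAV-iLuc replicate 3 (edgeR adjusted p = 0.103 and 0.0527) and in DESeq2 (0.105). Cd68 at 18.6 ± 2.77 against 15.3 ± 1.49 CPM, Lyz2 at 3.17 ± 1.04 against 2.04 ± 2.99 CPM and Fcer1g at 1.75 ± 0.72 against 1.17 ± 0.46 CPM did not pass. Lyz2 passed without AAV-iLuc replicate 1 (adjusted p = 0.00185) and Cd68 without AAV-iIL12 replicate 2 (adjusted p = 0.0212). The T and NK cell list had 1 tested member, Lck, which rose from 2.06 ± 0.64 to 5.27 ± 0.29 CPM. Without AAV-iIL12 replicate 3, 3 members were tested and 3 rose. Gzmb, a cytotoxic granule protease, stood at 1.01 ± 0.82 against 0.0520 ± 0.104 CPM, below the filter.

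In the dendritic cell list 1 of 3 tested members fell, also adjusted over the list alone, namely Fscn1, from 251 ± 26.0 to 156 ± 19.8 CPM (camera adjusted p = 0.600, median 0.05, mean -0.14). The median lay between -0.25 and -0.10 without AAV-iIL12 replicate 2 or AAV-iLuc replicate 1, 2 or 4, and was -0.04 and -0.03 with library size only and upper quartile scaling. Zbtb46 stood at 8.77 ± 1.39 against 7.47 ± 1.19 CPM and Batf3 at 0.543 ± 0.113 against 0.525 ± 0.155 CPM. In the fibroblast list 1 of 11 rose, also adjusted over the list alone, namely Pdpn, from 55.4 ± 2.15 to 69.7 ± 4.77 CPM (camera adjusted p = 0.822, median -0.06, mean 0.03), and the collagen genes Col1a1 (adjusted p = 0.178) and Col3a1 at 31.1 ± 17.8 against 54.3 ± 45.5 CPM did not pass. Both passed as lower with no low-count filter (adjusted p = 0.0108 and 0.0444), and the log2 fold change of Col3a1, -0.81, was -0.06 without AAV-iLuc replicate 3. The fibroblast median was 0.16 and 0.35 without AAV-iIL12 replicate 2 and 3 and 0.34 without AAV-iLuc replicate 3, with 2 rises in the last 2 settings, and -0.27 and -0.10 without AAV-iIL12 replicate 1 and AAV-iLuc replicate 4. It was -0.15 with library size only and -0.13 with upper quartile scaling. In this list 1 member fell without AAV-iIL12 replicate 1 or AAV-iLuc replicate 1. In the pericyte list 1 of 5 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.518). Its median was -0.39 and its mean 0.005. The median was -0.24 without AAV-iIL12 replicate 2 and 0.33 without AAV-iIL12 replicate 3, where 2 of 6 rose and 1 fell. Rises numbered 0 without AAV-iIL12 replicate 1 and 2 without AAV-iLuc replicate 1, and falls numbered 1 without AAV-iLuc replicate 1, 2 or 3 and 3 with library size only or upper quartile scaling. Cspg4 fell by 1.10 and Mcam stood at 79.5 ± 26.6 against 104 ± 7.18 CPM, passing without AAV-iIL12 replicate 1 (adjusted p = 6.89e-05). Of 3 tested keratinocyte genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.228): Dsp, a desmosome protein, by 1.46 and Sfn by 0.85, while Perp stood at 8.50 ± 1.25 against 8.68 ± 1.55 CPM. Of 2 tested endothelial genes Egfl7 fell, also adjusted over the list alone, from 14.8 ± 1.17 to 7.61 ± 0.71 CPM and Vwf stood at 20.5 ± 5.83 against 21.9 ± 2.80 CPM. In the B cell, erythroid and skeletal muscle lists 1, 1 and 2 members were tested and 0 passed in edgeR, also adjusted over the list alone. No member of the neutrophil or adipocyte list passed the filter, except 1 neutrophil gene without AAV-iIL12 replicate 1, which rose.

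None of the 20 composition measures passed after adjustment (smallest adjusted p = 0.114, exact permutation test). Since no exact p can lie below 0.0286, adjustment over 20 measures leaves this test little power. It does not show that the composition was equal. Mitochondrially encoded genes took 1.97 ± 0.10% of counts in AAV-iIL12 and 2.24 ± 0.06% in AAV-iLuc (exact p = 0.0286, the smallest the 35 splits can give). Summed CPM of the T and NK cell list was 8.85 ± 2.34 against 2.53 ± 1.30, that of the endothelial list 28.8 ± 6.05 against 37.3 ± 3.08, that of the keratinocyte list 18.8 ± 1.02 against 13.2 ± 1.11 and that of the dendritic cell list 166 ± 18.5 against 259 ± 27.2, each with the same exact p. The dendritic cell sum came mostly from Fscn1, while Zbtb46 and Batf3 did not pass, so it reflects that gene rather than the list. The sums of the macrophage list, 35.4 ± 10.2 against 24.1 ± 9.75 CPM, and of the all-leukocytes list, 10.2 ± 3.65 against 5.58 ± 5.24 CPM, each had an exact p of 0.229.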

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

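The tests of the patterns weighed in this part were chosen only after the results had been seen. Among 172 values tested in the 4 AAV-iLuc libraries, 28 had 1 library far from the other 3, and 27 of the 28 outlying values belonged to AAV-iLuc replicate 1. For independent, normally distributed values chance gives about 1 in 20. Many of these values come from genes of the same lists in the same 4 libraries, so they are not independent and that rate is no yardstick for their number. Most were interferon, MHC or leukocyte genes.

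In AAV-iLuc replicate 1, class II genes stood above the nearest library of the group: Cd74 at 90.2 against 8.28 CPM, H2-Aa at 36.7 against 2.58, H2-Ab1 at 23.3 against 1.81, H2-Eb1 at 22.7 against 1.92, H2-DMa at 12.7 against 1.75, H2-DMb2 at 0.468 against 0.0596 and Ciita at 10.4 against 1.04. Guanylate-binding proteins and other interferon-inducible genes stood out in the same library, with Gbp8 at 4.89 CPM, Gbp10 at 17.3, Gbp5 at 6.71, Gbp4 at 72.6, Igtp at 176, F830016B08Rik at 2.86, Apol6 at 7.59, Zbp1 at 30.3, Samhd1 at 64.1, Ifit2 at 50.0, Cxcl9 at 2.76 and Tnfsf10 at 1.14. So did the leukocyte genes Lyz2 at 6.50 CPM and Ptprc at 2.44, and the all-leukocytes sum at 13.4 against 3.97 CPM. A few counts alone set Il12b at 0.104 CPM, Ifng at 0.0520, Gzmb at 0.208, Csf3r at 0.312 and the haemoglobin share at 1.12e-04%. Hspa5 was highest in AAV-iLuc replicate 3, at 1336 against 1071 CPM.

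The first pattern weighed is the interferon state of AAV-iLuc replicate 1. RNA or index reads from the AAV-iIL12 libraries would have carried the interleukin 12 subunits along: a share of 7.27%, the median over the 39 interferon gamma genes, predicts 51.7 Il12a plus Il12b counts in this library, and it had 2. The all-leukocytes list, of which 8 of 10 genes passed the low-count filter, exceeded the other AAV-iLuc libraries by 10.4 CPM. That was 0.716% of the 1449 CPM by which the interferon gamma list did so. This argues against leukocytes carried through the CD45-negative sort as the source only if the list reaches a larger share in leukocytes. The data hold no sorted leukocytes to measure that share. For the class II genes of this library leukocytes cannot be told apart from other sources. The same 10.4 CPM were 6.26% of the excess of 166 CPM of H2-Aa, H2-Ab1, H2-Eb1 and Cd74, and the share in leukocytes is again unknown. A difference between animals, such as an interferon response without AAV-iIL12, may account for the interferon state of this library. No test bears on that and it stays a hypothesis.

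The second pattern weighed is the class II and interferon rise in cells sorted as CD45-negative, since class II genes are usually markers of antigen-presenting leukocytes. With a leukocyte score as a covariate, all 10 tested class II genes and 38 of 39 interferon gamma genes stayed past the threshold, and the all-leukocytes list summed to 0.298% of the CPM of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 in the AAV-iIL12 libraries. The score came from low-count genes of which 0 of 8 tested passed between the groups, so keeping these calls says little about leukocytes. The share argues against leukocytes as the whole source only if the list reaches a larger share in leukocytes, which was not measured. Expression by the tumour cells is a candidate explanation, and the counts do not show which cells carried the transcripts.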

How the results depend on the processing

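Across the alternatives run no gene called in both fits changed direction, and 2539 of 2609 comparisons of a named gene with an alternative kept its side of the threshold. The counts of 3292 higher and 3316 lower genes stayed within 1.5 times under all alternatives except a minimum absolute log2 fold change of 1, by construction, which left 817 higher and 654 lower. Leaving out each library gave 2898 to 3152 higher and 2774 to 3157 lower genes. With the leukocyte covariate 2419 genes rose and 2347 fell. The calls of Gch1, Il6, Ccng1, Xrcc5, Rad50, Aldoa and Atp5b were among those that ended there. All 15 list calls were lost with an estimated correlation, with adjusted p of 0.189 for cell death, complement, cytokine receptors, MHC class I, nucleic acid sensing and type I interferon, 0.223 for G1/S, 0.231 for checkpoint ligands and G2/M, 0.242 for interferon gamma, NF-kB and DNA repair, 0.251 for immediate early stress and 0.321 for chemokines and MHC class II. This setting changed only the correlation between genes. Its estimates for the called lists ran from 0.165 (cytokine receptors and JAK-STAT) to 0.914 (G2/M), against the preset 0.01. The main camera p values thus rest on a correlation lower than the one estimated. The list calls kept their direction and threshold with fry, library size only, no low-count filter, the replicate block and each library left out. List tests were not run under the other alternatives. With fry, 5 lists not called by camera passed: dedifferentiation (0.00110), keratinocytes (2.90e-04), oxidative phosphorylation (0.00685), pericytes (0.00899) and pigment (0.0123), since fry does not compare a list with other genes. Oxidative phosphorylation also passed with library size only (0.0323) and with no low-count filter (0.0301), and ranged from 0.0340 to 0.188 with a library left out, and dedifferentiation from 0.0480 to 0.218. The cause was not tested.

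The replicate numbers did not pair the libraries. Deviations from the group means correlated at 0.088, 0.034 and -0.049 for numbers 1, 2 and 3, and not every library correlated best with its own number. With the replicate block, where AAV-iLuc replicate 4 drops out, 2847 genes rose and 2800 fell, and no list call changed. At this depth Il12a, with 0 counts in AAV-iLuc, has only a bound.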

Other observations

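The tests in this part were chosen after the results had been seen, except the splits of the libraries. Genes inside and outside the fixed lists were also looked up by family. They were chosen after the values had been seen, and all calls named here held under the 3 other scalings. Psmb8, Psmb9 and Psmb10 were already counted in the class I list, Parp9 in the type I interferon list and Parp1 in the DNA repair list. The immunoproteasome subunits Psmb8, Psmb9 and Psmb10 rose by 4.62, 4.56 and 3.29 (5.80, 6.04 and 3.65 without AAV-iLuc replicate 1). The subunits they replace did not rise: Psmb5 fell from 43.1 ± 1.43 to 37.0 ± 1.61 CPM, Psmb7 fell from 121 ± 7.11 to 106 ± 3.06 CPM, and Psmb6 stood at 102 ± 1.07 against 110 ± 8.10 CPM, passing as lower with library size only or upper quartile scaling. The Psmb7 call ended without AAV-iIL12 replicate 1 or 3 (edgeR adjusted p = 0.0574 and 0.0661) and with the replicate block (0.0558). With the leukocyte covariate the calls of Psmb5 and Psmb7 ended (edgeR adjusted p = 0.0969 and 0.106). Psme3, a proteasome activator outside the interferon-inducible pair Psme1 and Psme2, fell by 0.31. Serpinb9, an inhibitor of granzyme B, rose from 8.31 ± 3.35 to 55.5 ± 5.09 CPM. Il15ra rose by 3.99 and Il15 by 1.71. Ifi203, Mndal and Ifi211, of the interferon-inducible 200 family, rose by 5.02, 4.57 and 5.06 (5.82, 5.38 and 6.03 without AAV-iLuc replicate 1).

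Within some families members moved apart. Parp9, Parp10, Parp11 and Parp12 rose by 2.74, 2.39, 2.22 and 2.82, while Parp1, the main repair member, fell by 0.79. Of the receptor kinases related to Axl, Tyro3 fell from 24.3 ± 1.03 to 10.2 ± 1.76 CPM and Mertk stood at 8.62 ± 0.85 against 9.90 ± 2.45 CPM. Beside Itga4, Itga6 fell by 1.01, while the abundant integrins Itgb1 at 743 ± 20.6 against 816 ± 58.4 CPM, Itgav at 663 ± 52.8 against 617 ± 38.6 CPM and Itgb3 at 96.5 ± 9.86 against 89.0 ± 11.1 CPM did not pass, except Itgb1 as lower with library size only (adjusted p = 0.0106) and upper quartile scaling (0.0235). Dnmt1 and Ezh2, which methylate DNA and histones, fell by 1.05 and 1.03.

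AAV-iLuc replicate 1 lay nearer to the AAV-iIL12 libraries in interferon genes than in cell cycle genes. On a log2 scale where the other 3 AAV-iLuc libraries average 0 and the AAV-iIL12 mean is 100, the median over the changed members of each list placed this library at 46.2 for interferon gamma, 50.8 for MHC class II and 27.4 for type I interferon. It stood at -6.56 for G2/M, 4.29 for G1/S and 2.53 for DNA repair. Other control libraries, each set against the remaining 3, also lay off 0: replicate 4 at -33.9 for interferon gamma, -30.1 for MHC class II and -22.7 for type I interferon, away from AAV-iIL12 and against a mean that includes replicate 1, and replicate 2 at 26.0 for G2/M and 18.2 for DNA repair. These are values of single libraries and carry no test.

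The remaining tests bear on the interleukin 12 counts and on chance. In each AAV-iIL12 library Il12b lay at least 8.80 times above the most abundant member of the all-leukocytes list. This argues against leukocytes, macrophages included, that carry these genes at or above the level of Il12b. The macrophage list does not decide the question. Il12b lay only 1.01 to 1.51 times above Cd68, its most abundant member. Yet Cd68 stood at 18.6 ± 2.77 CPM in AAV-iIL12 and 15.3 ± 1.49 CPM in AAV-iLuc, where Il12b was near absent. The next most abundant members, Lyz2 and Fcer1g, stood below Il12b in AAV-iIL12. The ratio of Il12b to Il12a counts was at least 1.34 in each of the 3 libraries. Its difference between them had an exact p of 0.279, by Fisher's test, which covers counting error only. A common source of both transcripts would give no difference, but that p does not show that the ratios are equal or the source single. Whether the transcripts came from the vector or from the endogenous genes of some cell type may be settled only with reads, and was not tested. Of the 35 splits of the 7 libraries into 3 and 4, only the real one gave as many changed genes, 6608. That rank corresponds to the smallest p the splits can give, 0.0286. In edgeR the highest of the other splits gave 0 genes, and up to 4770 genes at an unadjusted p under 0.05. Those splits mix the groups, which raises the spread within them, so their counts do not measure what chance gives. Chance is therefore not excluded by this comparison.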
